A study of Mus musculus with 2 samples.

How the data were processed

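H3K9me3, the trimethylation of lysine 9 on histone H3 that marks silenced chromatin, was profiled by chromatin immunoprecipitation and sequencing in the forebrain of B6NCrl mouse embryos at embryonic day 10.5. The labels give 1 group with 2 biological replicates, made from pools of 69 and 51 embryos of both sexes, with a fragment size range of 300 to 500 bp in each. No other tissue, stage or treatment belongs to the series, so the comparisons were made between the replicates, between the peak lists, and between the peaks and the genome they lie in.

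Per the text listings deposited with the samples, peaks were called on each replicate against a control file of its own, on both replicates pooled against both controls, and a replicated list was then derived from these 3 lists. The rule for calling a peak replicated, the peak caller, the aligner and the thresholds are not given in the sources used here. All coordinates are those of mm10, per the labels, and are printed counting from 1. Each peak carries a ratio, read here as the fold enrichment over control, which is the authors' deposited value; the listings name only the narrowPeak layout, in which this column is a signal value. The −log10 p and −log10 q values per peak are likewise the authors' own, as deposited, and start at about 2 for p. The files hold no read counts, so the depth of each library is unknown and no interval that needs it is given.

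Peaks on chromosomes 1 to 19, X and Y were analysed, 56474 of 56893 in the replicated list. Genes came from GENCODE M21 and sequence from GRCm38.p6, the same build as mm10, with lower-case letters read as repeats. The replicated list was the main peak set, and each replicate's own list was run beside it. A gene counted as marked when at least 1 bp of a peak lay in its body. Peaks, or genes in their place, were rotated within each chromosome in coordinates without assembly gaps, 1000 times with a fixed seed, a permutation that keeps widths and clustering. The p-values are two-sided, except for the one-sided overlap of the replicates, and the smallest possible are 0.002 and 0.001. Benjamini-Hochberg adjustment ran over the 4 feature classes, the base contents or the 19 gene lists, with a threshold of 0.05. The positions of peaks in zinc finger genes were compared by an exact two-sided binomial test. That test took genes of at least 5 kb, a minimum set after the data were examined so that the windows at both ends do not meet. Peaks within 5 kb were joined into domains, and genes within 1 Mb into loci.

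The gene lists, the tests, the alternatives and the rule for named genes were chosen before the data were examined, except those said in the text to have been chosen later. The rule names the 10 protein-coding genes of at least 2 kb with the most covered bodies, the 10 with the highest fold of any replicated peak, up to 4 marked members of each list with the most covered bases, and the 5 most covered domains. Genes also had to carry a peak in both replicate lists, and genes outside the rule are said to be so where they are named. Some lists share members: Rpl10l is a ribosomal and a germline gene, Magel2 an imprinted and a Mage gene, Zim1 an imprinted and a zinc finger gene, and Zfp809 and several Zscan4 genes are in both the 2-cell and the zinc finger list. The symbols Dux and Eif1a-ps were not found in the annotation, though Duxf3 was found and is in the 2-cell list. Tasor is there as Fam208a.

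Alternatives were a −log10 q of at least 2, a −log10 p of at least 5, other overlap rules (50% of either peak, or reciprocal), peaks joined across 1 kb, equal numbers of strongest peaks, each replicate's list alone, the pooled list, summits in place of midpoints, TSS ±1 kb in place of gene bodies, 10000 random lists matched on gene length in 20 bins, other end windows and other joining gaps of 1 and 20 kb. The tests were tried on simulated data. Of 200 unrelated lists of 50 genes, 3.0% were called at 0.05, and lists with peaks added to 25% of members were recovered in 80.0% of 10 runs, or 100.0% with peaks added to 50%. These lists were drawn at random from all protein-coding genes, so the error rate for families clustered in the genome was not simulated. Of 20 unrelated overlaps 5.0% had p under 0.05. For rotated peaks, 7.5% of 40 feature tests and 5.0% of 20 base content tests were called. All these unrelated data were made by rotating the replicated peaks, the same operation as in the tests. The rates therefore check the calculation and cannot show whether rotation suits real peaks. With 10% of peaks moved to promoters, the excess was recovered in 100.0% of 10 runs, and with 10% moved to GC-rich places in 90.0%. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.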

Results

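H3K9me3 in the mouse forebrain at embryonic day 10.5 was described by 4 peak lists, those of replicate 1, of replicate 2, of both pooled, and of replicated peaks. The replicates came from pools of 69 and 51 embryos. The replicate 1 list held 153039 peaks with a median width of 211 bp, covering 47.4 Mb or 1.79% of the gap-free genome. In replicate 2, 66112 peaks with a median width of 144 bp covered 12.4 Mb or 0.467%. The pooled list held 143058 peaks, and the replicated list 56893 peaks with a median width of 295 bp, covering 22.6 Mb or 0.855%. All 56893 replicated peaks were identical to pooled peaks. Replicate 1 thus had 2.31 times as many peaks as replicate 2 and 3.83 times as many covered bases, and only 21.2% of replicate 2 peaks, against 64.3% of replicate 1 peaks, reached a −log10 q of 2. Depth is unknown, so these counts do not compare the amount of the mark.

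How far the replicates marked the same places was compared first. Most replicate 2 peaks were found in replicate 1 as well: 43206 of 65568, or 65.9%, shared at least 1 bp, against 3.53% after shifting. The reverse share was 34334 of 152443 replicate 1 peaks, or 22.5%, against 1.44% after shifting. The Jaccard index of covered bases was 0.164, against 0.00495. In each case the permutation p was 0.001, the smallest that 1000 shifts can give, one-sided. Sharing was higher for stronger peaks, reaching 96.2% in the strongest 10% of replicate 2 peaks and 74.7% in that of replicate 1, against 49.6% and 6.74% in the weakest 10%. Across the 34334 shared peaks, which are not independent replicates, the authors' fold enrichments in the replicates had a Spearman correlation of 0.37 and a Pearson correlation of 0.53. Requiring a reciprocal overlap of 50% lowered the shares to 14.3% of replicate 2 and 6.16% of replicate 1 peaks, both still above the shifts.

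**Figure D1:**
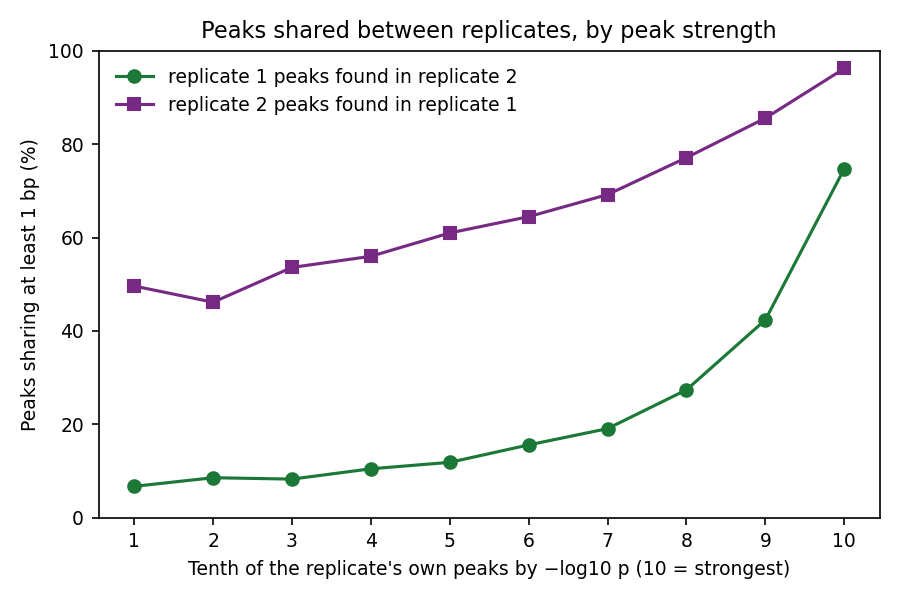
Share of each replicate's peaks (y axis, percent) with at least 1 bp in the other replicate's list, in 10 equal classes of its own −log10 p (x axis, 10 strongest); circles are replicate 1 and squares replicate 2. The share is 74.7% and 96.2% in the strongest classes and 6.74% and 49.6% in the weakest.

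The replicated list rested mostly on places seen in both replicates. Of its 56474 chromosomal peaks, 35432 (62.7%) overlapped peaks of both replicates, 19338 (34.2%) overlapped replicate 1 peaks alone, 1378 replicate 2 peaks alone and 326 neither. Of 142439 pooled peaks, 25.6% overlapped both replicates and 52.1% replicate 1 alone. Peaks of the pooled list that were left out of the replicated list were narrower, with a median of 130 bp against 295 bp, and had a lower median fold, 2.996 against 3.995.

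Chromosome 7 was covered most densely by called peaks and the sex chromosomes least. Chromosome 7 was covered 3.26 times as densely as all chromosomes together in the replicated list (2.86 ± 0.127 in the replicates, SD, n = 2), followed by chromosome 17 at 1.98 (1.91 ± 0.0319), chromosome 4 at 1.40 (1.34 ± 0.0710) and chromosome 13 at 1.39 (1.304 ± 0.00152). Chromosomes 1, 14 and 15 were at 0.506, 0.567 and 0.544. Chromosome X was at 0.281, with 0.522 in replicate 1 and 0.309 in replicate 2, and chromosome Y at 0.0300, with 0.0727 and 0.0310. Both chromosomes were less covered than every autosome in each list, which need not mean less of the mark: 96.3% of Y and 46.8% of X sequence is soft-masked, against 33.5% on autosomes, and pools of both sexes hold fewer copies of X and Y than of an autosome. No test was run, since there were 2 replicates. The SD of the ratio was largest on chromosome 18 (1.16 ± 0.151) and chromosome X (0.415 ± 0.150), while in relative terms the replicates differed most on chromosome Y.

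**Figure D2:**
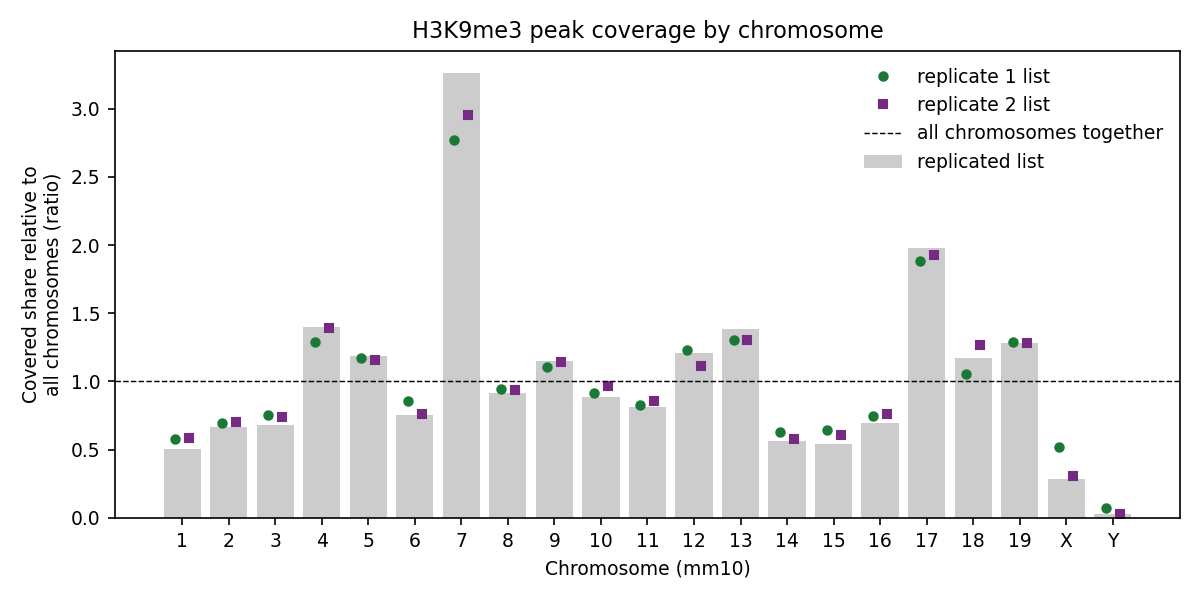
Covered share of each chromosome relative to all chromosomes together (y axis, ratio), by chromosome (x axis, mm10); bars are the replicated list, circles replicate 1, squares replicate 2, and the dashed line is 1. Chromosome 7 is at 3.26 and chromosome X at 0.281 in the replicated list.

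Peaks lay between genes more often, and in introns less often, than shifted peaks. Midpoints outside protein-coding genes and their promoters made up 68.5% of replicated peaks against 58.1 ± 1.67% (SD over shifts), a ratio of 1.18, and introns of protein-coding genes 25.5% against 36.5 ± 1.56%, a ratio of 0.698; both had adjusted permutation p = 0.004. Exons held 4.17% against 3.64 ± 0.245% (ratio 1.14, adjusted permutation p = 0.0453). Promoters, within 1 kb of a TSS, held 1.83% against 1.77 ± 0.157% (adjusted permutation p = 0.691). In replicate 1 alone the exon excess was not called (1.07, adjusted permutation p = 0.172), and in replicate 2 alone promoters exceeded the shifts (1.27, adjusted permutation p = 0.002).

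Peak sequence was richer in G and C than shifted sequence. G and C made up 46.1% of replicated peak bases against 42.1 ± 0.276% (adjusted permutation p = 0.004), with 45.6% in replicate 1 and 47.4% in replicate 2. Repeats, read from soft-masked letters, made up 34.8% against 34.0 ± 0.788% (adjusted permutation p = 0.316). The replicates lay on opposite sides of their shifts in repeats, at 37.4% in replicate 1 (34.2% shifted) and 32.0% in replicate 2 (34.0% shifted), each with adjusted permutation p = 0.002.

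Of 19 gene lists, 5 held more marked genes than shifted peaks gave: C2H2 zinc finger, vomeronasal receptor, clustered protocadherin, imprinted, and germline and meiosis genes. Each had a permutation p = 0.002, the smallest that 1000 shifts can give, two-sided, and adjusted permutation p = 0.00759. For comparison, 5294 of all 21938 protein-coding genes (24.1%) were marked.

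C2H2 zinc finger genes, a family that includes repressors of transposable elements, were marked in 231 of 421 cases, 2.32 times the 99.4 ± 14.9 (SD over shifts) expected, at 94 of 161 separate loci. In the replicates, 310 and 246 members were marked. Replicated peaks covered 29.0 kb of Zfp936 (chromosome 7, 43114229 to 43192109), or 37.3% of its body (35.3 ± 16.7% in the replicates, SD, n = 2). Zfp943 on chromosome 17 had 27.8 kb covered (25.6% of its body; 39.03% and 12.4% in replicates 1 and 2), Zfp180 on chromosome 7 had 19.7 kb (76.5%; 86.3% and 48.8%) and Zfp981 on chromosome 4 had 19.5 kb (52.2%; 61.8% and 35.04%). Around the TSS, 27 members were marked within 1 kb in the replicated list, 1.18 times the expected number, which ended the call (adjusted permutation p = 1.0). With the lists of replicates 1 and 2 alone, 76 and 43 members were marked there, which was not called either.

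Vomeronasal receptor genes, whose products detect pheromones, were marked in 131 of 326 cases, 2.12 times the expected 61.8 ± 16.2, at 17 of 26 loci. Vmn2r60, Vmn2r59 and Vmn2r53 on chromosome 7 had 21.4, 12.4 and 11.6 kb covered, and Vmn2r16 on chromosome 5 had 11.1 kb. These are 24.2%, 25.9%, 25.3% and 27.7% of their bodies, but replicate 2 alone covered 12.3%, 10.9%, 14.4% and 13.8%, and replicate 1 alone 39.4%, 41.96%, 40.2% and 46.99%. The call ended with replicate 1 alone, where 165 members were marked (1.41 times, adjusted permutation p = 0.0633), and with the pooled list (1.45 times, adjusted permutation p = 0.0531). Replicate 2 alone marked 136 members (1.82 times, adjusted permutation p = 0.019). At the TSS ±1 kb, 65 members were marked in the replicated list, 2.93 times the expected number (adjusted permutation p = 0.019). There the excess was called with replicate 1 alone (2.275 times, adjusted permutation p = 0.038) but not with replicate 2 alone (2.16 times, adjusted permutation p = 0.19).

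Clustered protocadherin genes, which encode cell-surface proteins that give neurons distinct identities, were marked in 53 of 56 cases, 2.39 times the expected 22.2 ± 11.6. The family forms 1 locus on chromosome 18 in which gene bodies overlap, so its members are not independent. Pcdhga1 (chromosome 18, 37661793 to 37841873) had 101.4 kb covered, or 56.3% of its body (50.5 ± 14.2% in the replicates, SD, n = 2), and Pcdhga2, Pcdhga3 and Pcdhgb1 had 97.3, 92.3 and 86.8 kb, shared in large part between them. All 56 members were marked in replicate 1 and 52 in replicate 2. In the symbol families described below, chosen after the results were seen, Pcdhb had 22 of 22 members marked against 1.20 expected. Pcdhga and Pcdha, marked in 12 of 12 members each, had 7.23 and 8.86 expected, so the named genes are not where the excess of marked bodies was largest. Within 1 kb of the TSS, 51 members were marked, 24.8 times the expected number (adjusted permutation p = 0.0127), and 10.9 times with replicate 1 alone.

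Imprinted genes, expressed from the maternal or the paternal copy, were marked in 37 of 46 cases, 2.60 times the expected 14.2 ± 3.28, at 20 of 20 loci, and in 40 members in each replicate, 1.70 times the expected number in replicate 1 alone. Kcnq1 and its antisense transcript Kcnq1ot1 on chromosome 7 had 19.6 and 17.03 kb covered and overlap each other. Gnas on chromosome 2 had 12.8 kb covered and Snrpn on chromosome 7 had 10.6 kb. The covered share of the body differed between replicates 1 and 2 at Kcnq1 (10.5% and 2.71%), Kcnq1ot1 (30.5% and 7.98%) and Snrpn (18.6% and 3.40%). Germline and meiosis genes were marked in 28 of 46 cases, 2.34 times the expected 11.98 ± 2.78, at 27 of 45 loci, with 35 and 31 members in replicates 1 and 2; the former is 1.54 times the expected number. D1Pas1, an intronless relative of the helicase gene Ddx3x on chromosome 1, had 77.9% of its body covered (64.2 ± 22.6% in the replicates, SD, n = 2). Tdrd1 had 1.74 kb covered (6.53% and 1.35% of its body in replicates 1 and 2), Taf7l 1.57 kb and Meioc 1.47 kb. Within 1 kb of the TSS the excess was larger for both lists: 22 imprinted genes, 8.62 times the expected number, and 21 germline genes, 11.7 times, each with adjusted permutation p = 0.0127, and 4.84 and 6.17 times with replicate 1 alone.

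The other 14 lists did not pass the test. Forebrain progenitor genes were marked in 1 of 36 cases (3.21 ± 1.66 expected, adjusted permutation p = 0.745), the exception being Foxg1, a telencephalic transcription factor, with 277 covered bp and a peak in replicate 1 alone; it lies outside the rule for named genes. Replicate 1 alone marked 10 members of this list and replicate 2 alone 2. Neuronal genes were marked in 9 of 28 cases (10.5 ± 2.12 expected, adjusted permutation p = 0.934), among them Slc17a7 with 2.92 kb, Bcl11b with 2.86 kb, Reln with 2.27 kb and Syt1 with 2.19 kb covered. In replicates 1 and 2 the covered shares of their bodies were 31.4% and 13.02%, 4.86% and 2.42%, 0.812% and 0.143%, and 0.790% and 0.253%. No progenitor or neuronal gene was marked within 1 kb of its TSS. The shifts gave only 1.17 and 1.01 such genes, and 4.08% of all protein-coding genes were marked there, so these zeros show no deficit. Hox genes were marked in 0 of 39 cases (2.99 ± 2.27 expected, adjusted permutation p = 0.591), with 1 and 3 marked in replicates 1 and 2. As 0 is the lowest possible count, the shift test of the replicated list could not have called a deficit of Hox genes (permutation p = 0.218). In replicate 1 alone, where 7.18 were expected, the ratio was 0.139 (adjusted permutation p = 0.103), which was not called. In replicate 2 alone 3.86 were expected.

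Olfactory receptor genes were marked in 152 of 1092 cases (104 ± 33.4 expected, adjusted permutation p = 0.591), led by Olfr139 and Olfr398 on chromosome 11 and Olfr1349 and Olfr1347 on chromosome 7. Against random lists matched on gene length, olfactory receptors were called as marked more often (1.43 times, adjusted permutation p = 0.001), and Hox and keratin genes as marked less often (0.0 times, adjusted permutation p = 0.0461, and 0.231 times, adjusted permutation p = 0.0266). Such random lists do not keep the clustering of these families. Keratin genes were marked in 2 of 109 cases (Krt32 and Krtap12-1), Rhox and Mage genes in 4 of 55 (Magel2, Rhox13, Magea2 and Mageb18), cytosolic ribosomal protein genes in 4 of 83, including Rpl3, Rpl10l and Rpl39l, and histone genes in 2 of 67, including Hist1h2be. Genes of the 2-cell stage were marked in 3 of 26 cases, Zfp809, Duxf3 and Zscan4a.

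For liver, blood, muscle and mesenchyme genes, neither an excess nor a deficit passed the test. A deficit could hardly show where few marked genes were expected, as for blood genes (3.39 ± 1.56). Liver genes were marked in 6 of 30 cases, with 10.95 kb covered in Cyp3a11 (57.9% and 16.6% of its body in replicates 1 and 2) and 6.79 kb in Serpina1b (16.7% and 2.70%), blood genes in 2 of 22 (Cx3cr1 and Gata1), muscle genes in 6 of 30, including Ttn and Ryr1, and mesenchyme, vessel and surface ectoderm genes in 5 of 24, including Pdgfrb and Col1a1. Of the genes for H3K9 methylation and silencing factors, 9 of 26 were marked, led by Atf7ip with 7.81 kb (12.98% and 4.44% of its body in replicates 1 and 2). The adjusted permutation p lay between 0.924 and 1.0 for these 5 lists.

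**Figure D3:**
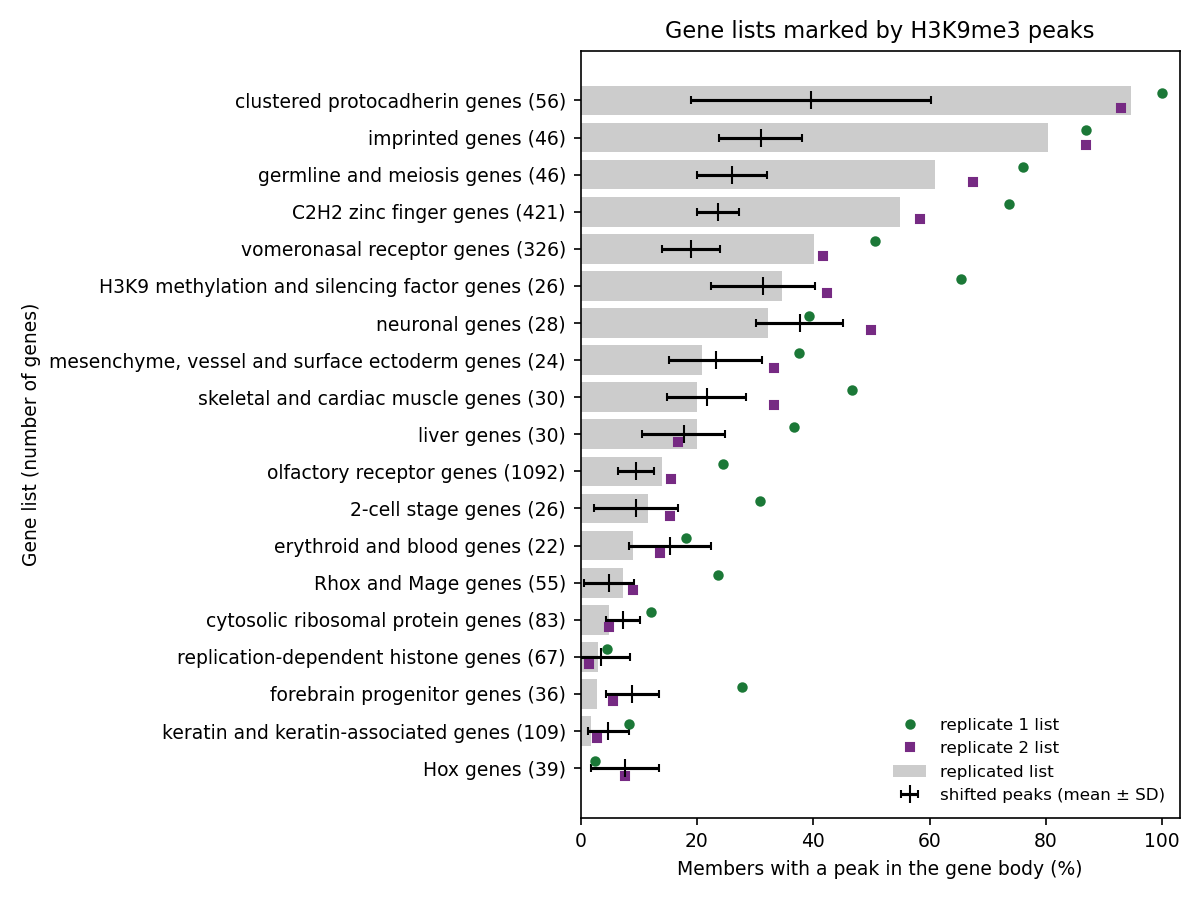
Percent of the members of each list with a peak in the gene body (x axis), by list with its number of genes (y axis); bars are the replicated list, circles replicate 1, squares replicate 2, and ticks with bars the mean ± SD of 1000 shifts of the replicated list. Protocadherin (94.6%) and imprinted genes (80.4%) stand highest and Hox genes (0.0%) lowest.

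Zinc finger genes with a peak at 1 end only had it at the 3′ end far more often than at the TSS. Of 395 genes of at least 5 kb, 131 had a peak in the last 2 kb, at 50 loci, 26 within 1 kb of the TSS, and 255 at neither end. A peak at the 3′ end alone was found in 114 genes and at the TSS alone in 9, so that 92.7% of genes with 1 end marked had it at the 3′ end (exact binomial p = 2.68e-24, two-sided). The share was 83.4% in replicate 1 and 82.8% in replicate 2. The strongest peak had its summit 23976 bp from the TSS in Zfp180 (25.8 kb long) and 34070 bp in Zfp981 (37.4 kb), but nearer the TSS in Zfp936 (14672 bp of 77.9 kb) and Zfp943 (9412 bp of 108.6 kb). Neighbouring genes are not independent, so the p-value is too small.

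**Figure D4:**
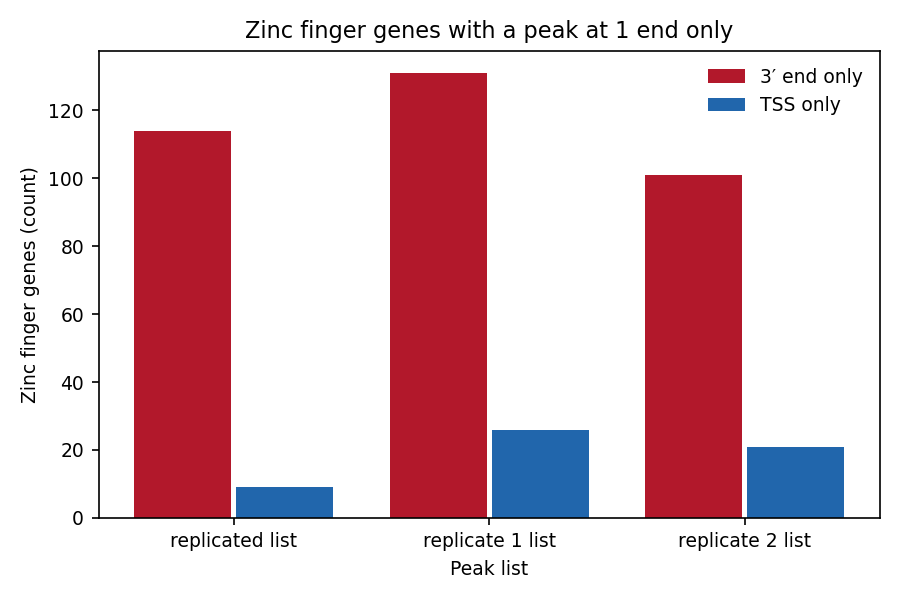
Number of zinc finger genes with a peak at 1 end only (y axis, count) in each peak list (x axis); red bars are the 3′ end and blue bars the TSS. The replicated list has 114 genes at the 3′ end only and 9 at the TSS only.

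Peaks lay close enough in places to be joined into domains. Across gaps of up to 5 kb, the replicated peaks gave 23671 domains, of which 1105 spanned at least 10 kb and 110 at least 50 kb. The domain with the most covered bases (chromosome 18, 37637337 to 37777858) had 111 of 141 kb covered (79.1%; 70.5 ± 21.5% in the replicates, SD, n = 2) and held the Pcdhga and Pcdhgb genes with Slc25a2 and Taf7. Next came a domain on chromosome 1 (88203223 to 88310878) with 83.8% covered (79.7 ± 9.96%, SD, n = 2) over the Ugt1a genes, which encode glucuronosyltransferases, and Mroh2a, Hjurp and Trpm8. The other 3 were on chromosome 4 (121562045 to 121735427, over Gm12887), chromosome 7 (14410247 to 14610641, over Sult2a8, Sult2a7 and Vmn1r90) and chromosome 10 (82083039 to 82240064, over BC024063, AU041133 and Zfp938), with 82.3, 80.8 and 72.98 kb or 47.5%, 40.3% and 46.5% covered. Replicate 2 alone covered 19.7%, 16.7% and 25.3% of these 3, and replicate 1 alone 63.1%, 59.1% and 60.2%. The number of domains of at least 10 kb depended on the joining gap, with 199 at 1 kb and 2927 at 20 kb, and on the list, with 2239 in replicate 1 and 980 in replicate 2. Domains of at least 50 kb likewise numbered 2 and 364 at these gaps, and 295 and 62 in replicates 1 and 2.

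The gene bodies covered most fully were those of Nnat (covered along its whole length; 86.8 ± 15.4% in the replicates, SD, n = 2), an imprinted gene on chromosome 2, Mroh2a (98.6%; 96.96 ± 3.57%, SD, n = 2) and Ugt1a1 (98.2%; 95.9 ± 5.77%, SD, n = 2). Gm21738, Pcdhb1, Pcdhb2, Scgb2b27, Scgb2b3, Asmt and Il3ra followed with 97.2% to 91.3%, though replicate 2 alone covered 52.6% of Pcdhb1, 47.7% of Scgb2b27 and 52.4% of Scgb2b3. Among single peaks of the replicated list, the authors' fold enrichment was highest in Ccdc177 on chromosome 12, at 19.7 (peak 80755815 to 80759556, summit in a coding exon), with 82.2% of the gene body covered. The peak at Tcfl5 on chromosome 2, with a fold of 19.5, had its summit outside the gene body, 291 bp from the TSS, and covered 0.337% of the body. Shroom3 on chromosome 5 (18.8), Trim71 on chromosome 9 (17.8) and Asmt on chromosome X (17.2) had summits in coding exons. A single peak on chromosome 18 (37746362 to 37751907, fold 16.9) accounted for the rest, Pcdhga1, Pcdhga10, Gm37013, Gm37388 and Gm42416, whose bodies overlap there. The order was not that of either replicate: among these genes Shroom3 was highest in replicate 1 (27.8, against 27.4 for Ccdc177) and Asmt in replicate 2 (13.5), followed by Tcfl5 and then Ccdc177 (19.7 ± 10.9 over the replicates, SD, n = 2). The folds differed over 2-fold between replicates 1 and 2 at Shroom3 (8.57 in replicate 2), Ccdc177, Trim71 (21.7 and 8.82) and the genes of chromosome 18 (21.3 and 9.33).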

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

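Peaks outside the assembled chromosomes are listed because the comparisons above left them out and they number more than the 3 that a count of 0 allows, which does not show that they are unusual. The replicated list held 419 peaks on unplaced and unlocalized contigs, on 28 of 44 contigs, of which 115 lay on the contig JH584304. That is 79.9 peaks per Mb of contig sequence against 21.3 per Mb of chromosomes, and the replicates had 596 and 530 such peaks. On the mitochondrial genome, the replicate 2 list had 14 peaks, with a median fold of 1.44, and the replicate 1 list had 0.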

How the results depend on the processing

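The alternatives at the TSS with each replicate's list or random protein-coding genes, and those without chromosome 7, were chosen after seeing the data. Over the main results, 197 values under an alternative counted as the same, 17 moved, 15 reversed, 5 passed the threshold anew and 8 no longer passed it. A tested value counted as the same if its direction and side of the threshold stayed, whatever its size. The share of replicate 2 peaks, 65.9% and 14.3% with a reciprocal 50% overlap, thus counted as the same. Untested values were judged by the replicate SD for chromosomes and by a fixed ratio for domain counts. A confidence interval served for the support of the lists, and equality after rounding for the correlation. The overlap of the replicates and the 3′ position in zinc finger genes held under every alternative run. The 3′ position was not run with the pooled list. No reversed result had passed its test with the replicated list.

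With each replicate's list alone, the values ran as follows: chromosome 7 from 2.77 to 2.95 times the genome, chromosome 17 from 1.89 to 1.93, X from 0.309 to 0.522 and Y from 0.0310 to 0.0727; promoters from 1.12 to 1.27 and exons from 1.07 to 1.38 times the shifts; soft-masked bases from 32.0% to 37.4%. Marked members over expected ran from 1.41 to 1.82 for vomeronasal, 0.668 to 1.12 for neuronal, 0.745 to 1.03 for liver, 1.21 to 1.26 for muscle, 0.838 to 1.11 for mesenchyme and 0.487 to 1.37 for progenitor genes. Domains of at least 10 kb ran from 980 to 2239, and marked protein-coding genes numbered 6647 and 9421.

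With the pooled list, chromosomes 7, 17 and 19 were at 2.93, 1.92 and 1.297, vomeronasal genes at 1.45 times the expected number, liver genes at 0.909, muscle genes at 1.11 and mesenchyme genes at 1.01. With a −log10 q of at least 2, chromosome 19 was at 1.27 and silencing factors at 0.916; with a −log10 p of at least 5, they were at 1.26 and 0.989, and 2-cell genes at 0.916. A 50% overlap of either peak gave 24.6% of pooled and 62.0% of replicated peaks in both replicates, and a reciprocal 50% overlap a Spearman correlation of 0.41. Joining gaps of 1 and 20 kb gave 199 and 2927 domains of at least 10 kb.

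At the TSS, zinc finger genes were at 1.18 and 2-cell genes at 0.637 times the expected number. In the TSS windows of replicates 1 and 2, zinc finger genes were at 1.59 and 1.79 and, with random protein-coding genes, at 1.58; vomeronasal genes in replicate 2 were at 2.16. None of these 4 was called (adjusted permutation p = 0.163, 0.19, 0.0842 and 0.19). Vomeronasal genes at the TSS were called with the replicated list, with replicate 1 alone and against random protein-coding genes. Random lists matched on gene length gave 1.43 for olfactory receptors, 0.0 for Hox, 0.231 for keratin and 0.617 for Rhox and Mage genes. Without chromosome 7, all 5 called lists stayed called, with zinc finger genes at 2.27 and vomeronasal genes at 2.15. No paired analysis was possible because there is 1 group. Depth is unknown, so its effect on the list lengths cannot be measured here.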

Other observations

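The tests of the sex makeup of the pools and of peaks without repeats, the families of gene symbols and the genes named in the next paragraph were chosen after the results were seen. Apart from the sex makeup of the pools, no biological explanation was tested for any pattern, since the design has 1 group.

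Of the 21 germline genes marked within 1 kb of the TSS, 20 had a peak there in both replicates, the exception being Mov10l1, with a peak in replicate 1. The highest folds at a TSS were at Dazl (11.7), which encodes a germ cell RNA-binding protein, D1Pas1 (10.3), Ddx4 (8.55) and Sycp1 (7.49), which encodes a synaptonemal complex protein. Among imprinted genes all 22 had a peak at the TSS in both replicates, with the highest folds at the neighbouring TSSs of Peg3 and Usp29 (11.1), Meg3 (10.99) and Nnat (10.6), and 2.996 at Igf2r. Of the liver genes, 4 were marked at the TSS, Cyp3a11 in both replicates and Serpina1a, Serpina1b and Serpina1c in replicate 1 alone.

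Grouping protein-coding genes by the letters their symbols start with gave 257 families of at least 10 members. The screen cannot show whether any single family passes, since the smallest p of 10000 shifts, 0.0002, becomes 0.0514 when adjusted over all families for a family that stands alone; the 1000 shifts of a first run could decide even less. An unadjusted p under 0.05 was found for 9 families, 6 with more and 3 with fewer marked members than expected. Continuous p-values would give 12.9 of 257 by chance. Some families could not fall under 0.05 even with 0 marked, such as Tlr (1.56 expected, permutation p = 0.319). The number given by chance is therefore lower and unknown, and the 9 cannot be weighed against it. The Zfp family had 223 of 394 members marked (permutation p = 0.0002, adjusted p = 0.0514). The Nlrp family, of innate immune and oocyte genes, had 12 of 17 marked (permutation p = 0.0314, adjusted p = 1.0), with 13 and 12 in replicates 1 and 2. The Dusp phosphatase family had 0 of 24 (permutation p = 0.022, adjusted p = 1.0) in the replicated list alone, with 9 and 5 in the replicates.

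Chromosome X was covered less in replicate 2 than in replicate 1. Annotated repeats go with the pattern in some values, since X sequence is 46.8% soft-masked against 33.5% on autosomes, and peaks of replicate 1 alone are 38.8% soft-masked against 28.4% for replicate 2 alone. The difference stayed for peaks with no soft-masked base, 1161 and 334 on X, so repeats inside the called peaks were not all of it. Their log2 ratio of X coverage relative to autosomes, replicate 1 over replicate 2, was 1.3 (jackknife SE over blocks of X 0.137), against 0.78 for all peaks. This cannot exclude reads from repeats beside a peak, since median peak widths of 211 and 144 bp are below the fragment range of 300 to 500 bp. The lengths of the lists were not made equal either. Replicate 1 peaks that replicate 2 lacked were 2.51 percentage points more soft-masked on X than on autosomes (jackknife SE 1.76), within 2 SE of the bound of 5 set for excluding repeats, so this value decides nothing. A different sex makeup of the pools would move X and Y in opposite directions, and both were higher in replicate 1, with a log2 ratio relative to the genome of 1.23 on Y (475 and 51 peaks) and 0.76 on X, or 0.87 and 0.26 with lists of equal length. It cannot be told apart from the length of the lists, which would raise both. The length of the lists stays open as well, and may account for part of it: the strongest replicate 1 peaks, as many as in replicate 2, covered X at 0.370, between 0.522 for the whole list and 0.309 for replicate 2. The controls, separate for each replicate, were not examined.

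Zinc finger genes with 1 end marked had it mostly at the 3′ end. A preference of peaks for the 3′ ends of all genes does not account for this over all zinc finger genes: of other protein-coding genes of matched length with 1 end marked, 56.1% had it at the 3′ end, against 92.7% (Fisher's exact p = 2.18e-15). Neighbouring genes are not independent, so this p-value is too small as well. Reads shared between neighbouring paralogs may contribute and cannot be told apart from a mark on each gene, since isolated genes were few. Only 15 zinc finger genes with no other member of the list within 1 Mb had 1 end marked. Of these, 73.3% had it at the 3′ end (exact 95% interval 44.9% to 92.2%). That interval includes the 56.1% of other genes, so for isolated zinc finger genes the general preference is not excluded. Of all 102 isolated genes, 13.7% had a peak at the 3′ end. This lies between 33.2% of all zinc finger genes and 3.92% of other genes of matched length, and was not tested.

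Repeats made up more of the replicate 1 peaks than of shifted peaks and less of the replicate 2 peaks. Weak peaks of the longer list were not the difference, as the strongest replicate 1 peaks, as many as in replicate 2, were 37.5% soft-masked, against 32.0% in replicate 2. The GC content of the recovered fragments could contribute: peaks of replicate 2 alone had 2.12 percentage points more G and C than those of replicate 1 alone (jackknife SE over chromosomes 0.184), far above the 0.5 under which it would be excluded. The difference exceeds the bound of 2, set in advance for it to count as a cause, by less than this error, itself computed after the value was seen, so the explanation stays open. The same peaks differ in repeats, at 28.4% soft-masked in replicate 2 alone and 38.8% in replicate 1 alone. The value therefore cannot tell whether the GC difference is a cause of the repeat difference or follows from it. Shared peaks differed in the same directions, with 47.35% G and C in replicate 2 and 45.67% in replicate 1. They were 33.14% and 35.45% soft-masked, so neither difference is confined to places found in 1 replicate alone.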
